A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

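The 4 samples were total RNA from S. pombe, 2 of the wild-type strain and 2 of P41nmt1-rpb7+, grown overnight and then for a further 12 hours in fresh medium with 15 uM thiamine, per the labels' protocols. Also per the labels, 500 ng of RNA were reverse transcribed with an oligo-dT primer carrying a T7 promoter, and the amplified RNA was labelled with Cy3, 1 dye per array. The array is an Agilent design for S. pombe, with 15208 spots besides the controls. These spots carry 6892 different probes for 6791 loci, of which 6740 have 1 probe. The reference table of gene names (assembly ASM294v3) matched 6622 loci, and the other 169 kept the names in the files. The genome build behind the probes is not given in the sources used here, so no coordinates are printed.

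The deposited scanner files give each spot's intensity on a linear scale. Per the file headers, the images were extracted with Agilent Feature Extraction 11.5.1.1, which subtracted a background estimated from negative controls and corrected spatial trends, with no scaling between arrays. The deposited flags, values of 0 and 1 with no other unit, say per the file headers whether a spot is well above background, saturated or an outlier. The authors' series table holds log2 values, 1 per probe. Set against the scanner values, each column was log2 of the mean processed signal of a probe minus 1 constant per array for 87.1% to 88.8% of probes (within 0.01), and its 75th percentile was near 0. Its medians were −1.90 and −1.98 for the wild type and −1.96 and −1.99 for P41nmt1-rpb7+. Its exact centring and filters stay unknown, and it served only as an alternative.

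For the comparison, log2 of the processed signal minus the 75th percentile of each array over all spots but controls was used. Spots flagged as non-uniform or as population outliers were left out, and saturated spots were kept. Spots of one probe were averaged, and a probe entered if it was well above background on at least 2 of the 4 arrays. Different probes of a gene were averaged on the log2 scale, and of 47 genes with several probes tested, 9 had probes that changed in opposite directions. Of the genes tested, 75 lacked a value on 1 or more arrays. The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual degrees of freedom, and moderation across genes added 2.53. The arrays were scanned in 2 scans of 1 slide, and each scan held 1 strain.

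A gene whose probes were not well above background on any array of a strain has only a bound there. Its fold is given as "at least", as the mean normalised log2 signal of the brighter strain against the mean, over the dimmer strain's arrays, of the higher of 2 values, the array's lowest signal among probes well above background and the gene's own. Where a gene was saturated on both arrays of the brighter strain, the fold is likewise a lower bound.

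The genes named were chosen by a rule fixed before the data were examined. It takes rpb7, the 12 largest increases and the 12 largest decreases among genes past the threshold whose arrays do not overlap between strains, and up to 4 called members with the largest change of each of 24 gene lists, also fixed beforehand. Some genes the rule takes are not reported here. The genes pts1, rpt4 and pho84, the classes of RNA and the genes in the last part were chosen after their values were seen. Of the list names, 5 had no match on the array and 6 were left out because another gene bears the name. Lists with at least 4 tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, with Benjamini-Hochberg adjustment over 23 lists.

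The fit and the list test were tested on simulated data before use. For P41nmt1-rpb7+ against the wild type, values were drawn independently for 5419 genes with the measured means and the moderated variances, and 200 genes were changed. Of those changed by a log2 size of 0.5, 52.2% were called, against 97.0% at a size of 1 and 66 of 66 at a size of 2, each in the right direction. A further 15 unchanged genes were called, 7.89% of all 190 calls, which also held 9 genes of a simulated list. That list, of 30 genes that moved together, was called, and 0 of 20 unchanged lists were. The simulated genes varied independently and few were changed, so false calls of lists with correlated genes were not measured.

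Alternatives fixed before the data were examined were scaling by the median or by the E1A spike-in probes, quantile normalisation, and normexp background correction with an offset of 50. Further ones were no filter on dim probes, probes well above background on all 4 arrays, the brightest probe per gene, the authors' log2 table, moderation with trend and robust options, the replicate number as a block, and each array left out in turn. A minimum change of 2-fold, a fit per probe and camera with an estimated correlation were also set out then. Probes with the specific tag only, a common background floor, leaving out the mitochondrial genome and spike-in scaling with the median shift of all genes taken off were added after the data were seen. Probe names carry the tag Spec (5212 probes) or Xhyb (1679 probes), whose meaning the files do not state. The probe of rpb7 carries Xhyb.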

Results

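Gene expression in fission yeast (Schizosaccharomyces pombe) was measured on 4 one-colour expression arrays, 2 from the wild-type strain and 2 from a strain of the same background called P41nmt1-rpb7+. In that strain rpb7, which encodes a subunit of RNA polymerase II, stood under the nmt1 promoter in its medium-strength form, which thiamine represses. Both strains were grown in medium with 15 uM thiamine, and the labels call the 2 samples of each strain biological replicates. The 75th percentile of the processed signal was 6174 and 5291 on the wild-type arrays and 5688 and 5247 on the P41nmt1-rpb7+ arrays. Of the spots, 84.2% and 78.6% of the wild type's and 80.3% and 78.5% of P41nmt1-rpb7+ were well above background. Arrays of one strain were close to each other, with an SD of the log2 difference across genes of 0.27 between the wild-type arrays and 0.27 between the P41nmt1-rpb7+ arrays, against 1.27 to 1.36 between arrays of different strains. The comparison addressed the transcriptional response to a low level of Rpb7, which the series' title ties to the response to DNA damage.

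The rpb7 transcript was lower in P41nmt1-rpb7+ on both arrays. Its normalised log2 signal was 0.06 ± 0.13 (SD, n = 2) in the wild type and −2.54 ± 0.35 (SD, n = 2) in P41nmt1-rpb7+, 6.03-fold lower. The processed signals of its probe were 6029 and 5848 in the wild type and 1161 and 763.2 in P41nmt1-rpb7+, so that it stayed well above background. The log2 fold change was −2.59 ± 0.19 (SE; limma, Benjamini-Hochberg adjusted p = 0.000548).

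Expression differed between the strains across most of the genome. Of 5494 genes tested, 3990 passed the threshold, 2139 higher and 1851 lower in P41nmt1-rpb7+ (limma, adjusted p under 0.05), and of these 1020 were at least 2-fold higher and 718 at least 2-fold lower. The strongest increases included transfer RNAs of the mitochondrial genome, the protein genes lsd90 and SPCC737.04, and several genes whose probes were not well above background in the wild type. The strongest decreases included the proline permease gene put4, the predicted nicotinic acid transporter gene SPAC11D3.18c and the neighbouring 5-oxoprolinase gene SPAC11D3.14c. All levels are relative to the 75th percentile of each array. When the arrays were scaled to the E1A spike-in controls instead, the median log2 fold change of all genes moved from 0.06 to −2.46 and the calls became 252 higher and 5053 lower, so "rose" and "fell" stand for changes relative to the bulk of the transcripts.

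**Figure D1:**
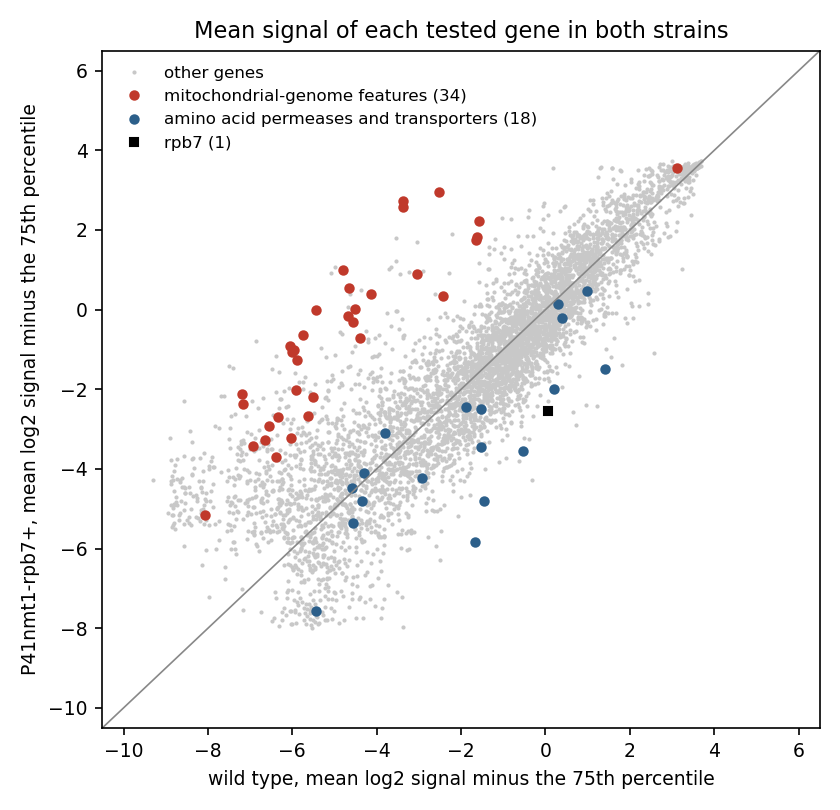
Mean normalised log2 signal of each tested gene in the wild type (horizontal axis) and in P41nmt1-rpb7+ (vertical axis), both as log2 signal minus the 75th percentile of the array, with the line of equal signal. The 34 features of the mitochondrial genome lie above the line, and rpb7 lies below it.

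Among the largest increases with a measured level in both strains, the mitochondrial glycine tRNA SPMITTRNAGLY.01 was 69.0-fold higher (log2 fold change 6.11 ± 0.10 SE; limma, adjusted p = 7.35e-05). SPCC737.04, a member of a protein family specific to S. pombe, was 66.8-fold higher and lsd90 was 64.3-fold higher. The mitochondrial tRNAs for aspartic acid (SPMITTRNAASP.01), phenylalanine (SPMITTRNAPHE.01) and leucine (SPMITTRNALEU.01) were 62.2-fold, 54.7-fold and 44.2-fold higher. The other 6 of the 12 largest increases were not well above background on either wild-type array, so they have only a lower bound. Each rests on 1 probe whose position in the gene could not be checked, so the bound holds for the probe's signal. The SUMO E3 ligase gene pli1 was at least 57.6-fold higher (adjusted p = 0.000113), the centrin gene cdc31 at least 47.7-fold, and the SWI/SNF and RSC subunit gene ssr3 at least 18.8-fold. The acetyltransferase-family gene SPBC577.03c was at least 31.5-fold higher, and the antisense RNAs SPNCRNA.1030 and SPNCRNA.652 at least 36.1-fold and 33.4-fold. In all, 148 of the genes called higher were not well above background on either wild-type array, and 172 of those called lower were not well above background on either P41nmt1-rpb7+ array.

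Among the largest decreases with a measured level in both strains, the permease gene put4 was 17.9-fold lower in the mean (−4.16 ± 0.65 SE; limma, adjusted p = 0.00441). Its signal lay below the background floor of P41nmt1-rpb7+ replicate 2, and its log2 fold change was −3.19 without that array and −5.13 without replicate 1. The isoleucine biosynthesis gene mmf2 was 15.6-fold lower, and without replicate 2 it fell more (−3.41) than put4. The predicted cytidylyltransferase gene cab4 was 13.8-fold lower, SPAC11D3.18c 12.6-fold, SPAC11D3.14c 12.4-fold and cbm1, which encodes a protein with a cellulose-binding domain, 12.1-fold lower. With 1 P41nmt1-rpb7+ array left out, cab4 was 9.06-fold to 21.1-fold lower and SPAC11D3.14c 7.87-fold to 19.7-fold. The other 6 of the 12 largest decreases were not well above background in P41nmt1-rpb7+. The intergenic RNA SPNCRNA.1308 was at least 9.67-fold lower, the cell surface glycoprotein gene pfl7 at least 9.44-fold, mug146 at least 7.75-fold, SPCC576.19c at least 6.93-fold, the intergenic RNA SPNCRNA.1316 at least 6.83-fold and dgc1 at least 6.66-fold lower.

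**Figure D2:**
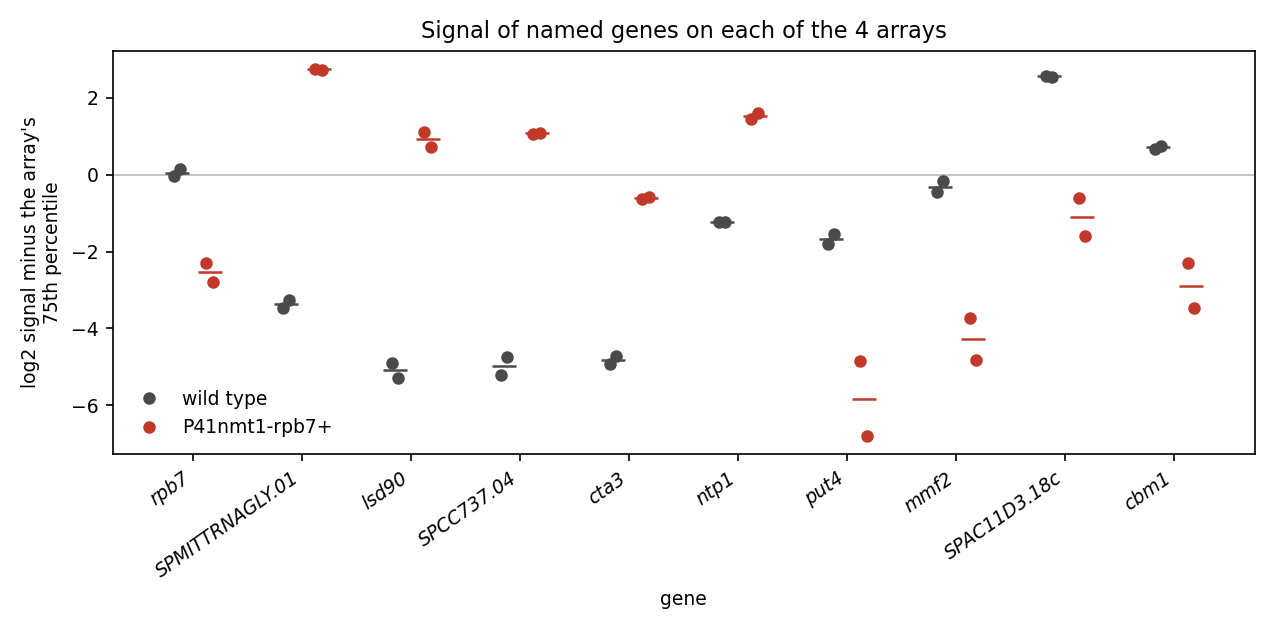
Normalised log2 signal (vertical axis, log2 signal minus the 75th percentile of the array) of 10 named genes on each of the 4 arrays, with points for arrays and bars for the mean of the 2 arrays of a strain. Both P41nmt1-rpb7+ arrays lie below both wild-type arrays for rpb7 (means −2.54 and 0.06) and put4 (means −5.82 and −1.66), and above them for SPMITTRNAGLY.01 (means 2.74 and −3.37).

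The genes for the subunits of RNA polymerase II, to which Rpb7 belongs, moved in both directions. Of 12 tested, 6 rose and 4 fell, the same counts as when adjusted over the list alone. The signal of rpb3 rose by 4.97 ± 0.10 (log2 fold change ± SE, as in the following paragraphs) from near background, on 1 probe whose position in the gene could not be checked, while rpb9 (at least 2.13-fold lower) and rpb8 (−1.03 ± 0.12) fell. No subunit gene of RNA polymerase III rose and 6 of 11 fell, both over all genes and adjusted over the list alone, with rpc11 (−1.66 ± 0.08) and rpc19 (−1.01 ± 0.09), which RNA polymerase I shares, changing most, followed by rpc82 (−0.58 ± 0.08) and rpc17 (−0.46 ± 0.09). The Mediator, which links activators to RNA polymerase II, had 4 of 14 subunit genes higher and 5 lower, again also adjusted over the list alone. The cyclin gene srb11 (−1.92 ± 0.14), med18 (−1.02 ± 0.08) and med31 (−0.96 ± 0.08) fell and med10 was at least 1.86-fold lower. None of the 3 lists passed the set test against the other genes (camera, adjusted p = 0.822 for RNA polymerase II, 0.152 for RNA polymerase III and 0.809 for Mediator). A self-contained test of whether the genes of a list moved one way on balance, which makes no comparison with other genes, gave adjusted p = 0.0161 for both polymerases and 0.0687 for Mediator (fry). The RNA polymerase II list had a median of 0.24 and a mean of 0.25. It holds rpb7 itself (−2.59 ± 0.19), repressed by the strain's design, and the unchecked probe of rpb3. The self-contained test was not repeated without rpb7 and rpb3. For RNA polymerase II it thus does not show a shift shared by the subunit genes. The Mediator genes had a median of 0.09 but a mean of −0.16, and the direction of their test was down.

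Genes of the DNA damage response changed in both directions, and neither list stood apart from the other genes. Of 19 checkpoint genes tested, 6 rose and 4 fell, also when adjusted over the list alone. The checkpoint scaffold gene rad4 rose (3.93 ± 0.08), as did the ATR kinase gene rad3 (0.92 ± 0.10), and rad1, which encodes a part of the checkpoint clamp, was at least 5.17-fold higher. The gene of another clamp subunit, rad9, fell (−1.35 ± 0.08). Of 49 DNA repair genes, 10 rose and 21 fell, also when adjusted over the list alone. The ubiquitin ligase gene rhp18 (3.39 ± 0.09) rose, whereas rad15 (−1.48 ± 0.25), a TFIIH subunit of nucleotide excision repair, and rhp26 (−1.36 ± 0.11), which acts in transcription-coupled repair, fell. The increases of rad4, rad3, rad1 and rhp18 each rest on 1 probe with the tag Xhyb, whose meaning is not stated. The probes of rad9, rad15 and rhp26 carry the tag Spec. The set test gave adjusted p = 0.767 for the checkpoint list and 0.301 for the repair list (camera). The self-contained test gave adjusted p = 0.00469 for the checkpoint list and 0.103 for the repair list (fry). The checkpoint list had a mean log2 fold change of 0.35 but a median of only 0.09. Its test was not repeated without the largest rises, rad4 and rad1, so it does not show a shift shared by the checkpoint genes.

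Subunits of the proteasome, the main protease for ubiquitin-tagged proteins, rose together. Of 33 genes tested, 27 rose and 2 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 0.62 (1.53-fold). The core subunit genes pre8 (4.03 ± 0.34) and pre9 (1.24 ± 0.09), the ubiquitin receptor gene rpn10 (2.83-fold higher) and the tethering factor gene cut8 (1.57 ± 0.13) changed most, and pts1 (−0.32 ± 0.10) and rpt4 (−0.30 ± 0.10) fell. The set passed the competitive test (camera, adjusted p = 0.00104), but not with an estimated correlation, 0.22 (camera, adjusted p = 0.926). No list passed in that form. It rests on 2 residual degrees of freedom and so says little about a single list.

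Heat shock and stress genes were mostly higher, without passing the set test against the other genes. Of 12 genes for heat shock proteins and chaperones, 8 rose and none fell, also adjusted over the list alone. The Hsp70 gene ssa1 (2.32 ± 0.12) and the disaggregase gene hsp104 (1.07 ± 0.18) rose, and the co-chaperone gene wos2 and the Hsp90 gene hsp90, saturated on both P41nmt1-rpb7+ arrays, were at least 2.18-fold and at least 1.93-fold higher. Of 20 core environmental stress response genes, 13 rose and 4 fell, also adjusted over the list alone. The calcium ATPase gene cta3 (4.21 ± 0.11), the nuclear envelope protein gene ish1 (2.85 ± 0.16) and the trehalase gene ntp1 (2.74 ± 0.09) rose, while the glutathione transferase gene gst1 was at least 5.61-fold lower. Both lists had adjusted p = 0.0997 in the set test (camera), while the self-contained test (fry) gave adjusted p = 0.00469 for the stress response and 0.0651 for heat shock.

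Genes repressed by glucose, phosphate, iron or thiamine did not pass the set test as groups. Of 12 glucose-repressed genes, 6 rose and 4 fell (6 and 5 adjusted over the list alone), among them the hexose transporter gene ght6 (4.01 ± 0.19), the invertase gene inv1 (2.36 ± 0.13), the malic enzyme gene mae2 (1.87 ± 0.23) and the hexose transporter gene ght1 (−1.44 ± 0.17). Of 7 phosphate starvation genes, 4 rose and 1 fell, also adjusted over the list alone. The transporter gene tgp1 (2.20 ± 0.26), the acid phosphatase gene pho1 (1.53 ± 0.10), the transcription factor gene pho7 (1.03 ± 0.08) and the polyphosphate synthesis gene vtc4 (0.60 ± 0.11) rose, and pho84 (−0.43 ± 0.13) fell. Of 11 iron uptake genes, 5 rose and 3 fell, also adjusted over the list alone, including shu1 (3.40 ± 0.33), the iron permease gene fip1 (1.66 ± 0.21) and the siderophore transporter genes str2 (0.91 ± 0.14) and str1 (−0.80 ± 0.17). Of 7 thiamine-repressed genes, 1 rose and 4 fell, also adjusted over the list alone, with thi4 (1.36 ± 0.11) higher and thi1 (−0.90 ± 0.09), pho4 (−0.66 ± 0.12) and thi5 (−0.65 ± 0.09) lower. Adjusted p in the set test was 0.868 for glucose, 0.386 for phosphate, 0.754 for iron and 0.501 for thiamine (camera). In the self-contained test only the phosphate list passed (fry, adjusted p = 0.0427), against 0.103 for glucose, 0.0687 for iron and 0.201 for thiamine.

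Genes of meiosis and nitrogen starvation were split, with 7 of 19 higher and 7 lower (8 and 8 adjusted over the list alone). The meiotic genes spo5 and rec8, not well above background in the wild type, were at least 8.03-fold and at least 9.33-fold higher, and the amino acid permease gene isp5 (−3.01 ± 0.26) fell, while inv1, already among the glucose-repressed genes, rose. Of 5 genes tested on the list set beforehand for the M mating type, 1 rose and 2 fell, also adjusted over the list alone. The assignment of genes to the M and P lists was not checked. The M-factor precursor gene mfm2 (−2.87 ± 0.25) and the transporter gene mam1 (−0.51 ± 0.09) fell, and the protease gene sxa1 (1.33 ± 0.10) rose. Among P mating-type genes 2 were tested, too few for the set test, and the receptor gene map3 (−0.82 ± 0.12) fell. The set test gave adjusted p = 0.946 for meiosis and nitrogen starvation and 0.508 for the M genes (camera).

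Translation and ribosome synthesis genes did not pass the set test. Of 128 genes for cytoplasmic ribosomal proteins, 10 rose and 32 fell (6 and 28 adjusted over the list alone), and 49 were saturated on all 4 arrays and so could not show a change. The largest changes were in rpl2701 (at least 4.98-fold lower), rps601 (−2.73 ± 0.13), rpl2502 (−2.70 ± 0.13) and rpl1603 (3.29 ± 0.11). Of 63 genes of ribosome biogenesis and RNA polymerase I, 16 rose and 21 fell (15 and 20 adjusted over the list alone), with utp24 at least 13.3-fold higher and the exosome subunit gene rrp42 (3.02 ± 0.12), rrp14 (1.97 ± 0.09) and nop2 (1.68 ± 0.08) also higher. Of 14 glycolysis genes, 5 rose and none fell (4 and 0 adjusted over the list alone), and 6 were saturated on all arrays. The enolase gene eno102 (3.51 ± 0.17), the glyceraldehyde 3-phosphate dehydrogenase gene gpd3 (1.70 ± 0.09) and the hexokinase gene hxk1 (0.38 ± 0.08) rose, and the pyruvate decarboxylase gene pdc201 was at least 5.99-fold higher. Adjusted p was 0.288 for ribosomal proteins, 0.501 for ribosome biogenesis and 0.346 for glycolysis (camera). The test of the ribosomal protein genes pointed down with a median of 0.04 and a mean of −0.21, and that of ribosome biogenesis pointed down with a median of −0.04 and a mean of 0.01.

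Of 21 mRNA decay factor genes, 5 rose and 7 fell, also adjusted over the list alone. The decapping enhancer gene edc3 (3.81 ± 0.28) and the helicase gene ste13 (1.47 ± 0.09) rose, the decapping enzyme gene dcp2 was at least 4.79-fold higher, and not1 (−1.26 ± 0.11), the scaffold of the deadenylase complex, fell. The list did not pass (camera, adjusted p = 0.754), its test pointing down with a median of −0.02 and a mean of 0.21.

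Features of repetitive DNA rose, although the heterochromatin factors did not pass the set test. Of 13 subtelomeric and Tf2 retrotransposon features, 12 rose and none fell, over all genes and adjusted over the list alone. The subtelomeric helicase family was highest, with tlh1 at least 18.4-fold higher and tlh2 up by 3.86 ± 0.16, while the Tf2 elements rose by less, the most in Tf2-10 (0.53 ± 0.10) and Tf2-11 (0.52 ± 0.08). Copies of these features are nearly identical, so the values of single copies are uncertain and the members are not independent. The set passed the competitive test (camera, adjusted p = 0.0142), but not after quantile normalisation (adjusted p = 0.153). Nor did it pass with probes above background on all arrays (adjusted p = 0.0501), or with spike-in scaling and the shift of all genes taken off (adjusted p = 0.0549). It also did not pass with an estimated correlation (camera, adjusted p = 0.926). That correlation was −0.07, below the preset 0.01, so correlation between its genes was not the reason. Of 20 genes for heterochromatin and RNA interference factors, 3 rose and 8 fell, also adjusted over the list alone, with adjusted p = 0.316 in the set test. The helicase gene hrr1 (3.10 ± 0.13) rose, and arb2 (−1.74 ± 0.17) and clr1 (−1.31 ± 0.12) fell.

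Of 10 histone genes, 3 rose and 4 fell, also adjusted over the list alone, with hht1 (−1.10 ± 0.10), hhf1 (−0.96 ± 0.09) and hhf3 (−0.92 ± 0.11) lower and hta2, saturated on both wild-type arrays, at least 2.11-fold lower. Among 17 targets of the MBF transcription factor and DNA replication genes, 7 rose and 5 fell, also adjusted over the list alone. The cohesin gene rad21, with a value on 1 of the 2 wild-type arrays, was at least 13.1-fold higher, the MBF corepressor gene nrm1 (1.89 ± 0.08) and the nuclease gene ctp1 (1.15 ± 0.12) rose, and the DNA polymerase delta gene cdc6 was at least 2.96-fold lower. Of 15 cell separation genes, 5 rose and 8 fell (5 and 9 adjusted over the list alone). The glucanase genes agn1 (−1.59 ± 0.12) and eng1 (−1.10 ± 0.14), whose enzymes open the septum, fell, the Polo kinase gene plo1 was at least 1.36-fold lower, and spo12 rose (5.23 ± 0.10). Adjusted p in the set test was 0.754 for histones, 0.946 for MBF targets and 0.605 for cell separation (camera). The histone genes' test pointed down with a median of 0.04 and a mean of −0.23, and that of the cell separation genes pointed down with a median of −0.26 and a mean of 0.06.

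**Figure D3:**
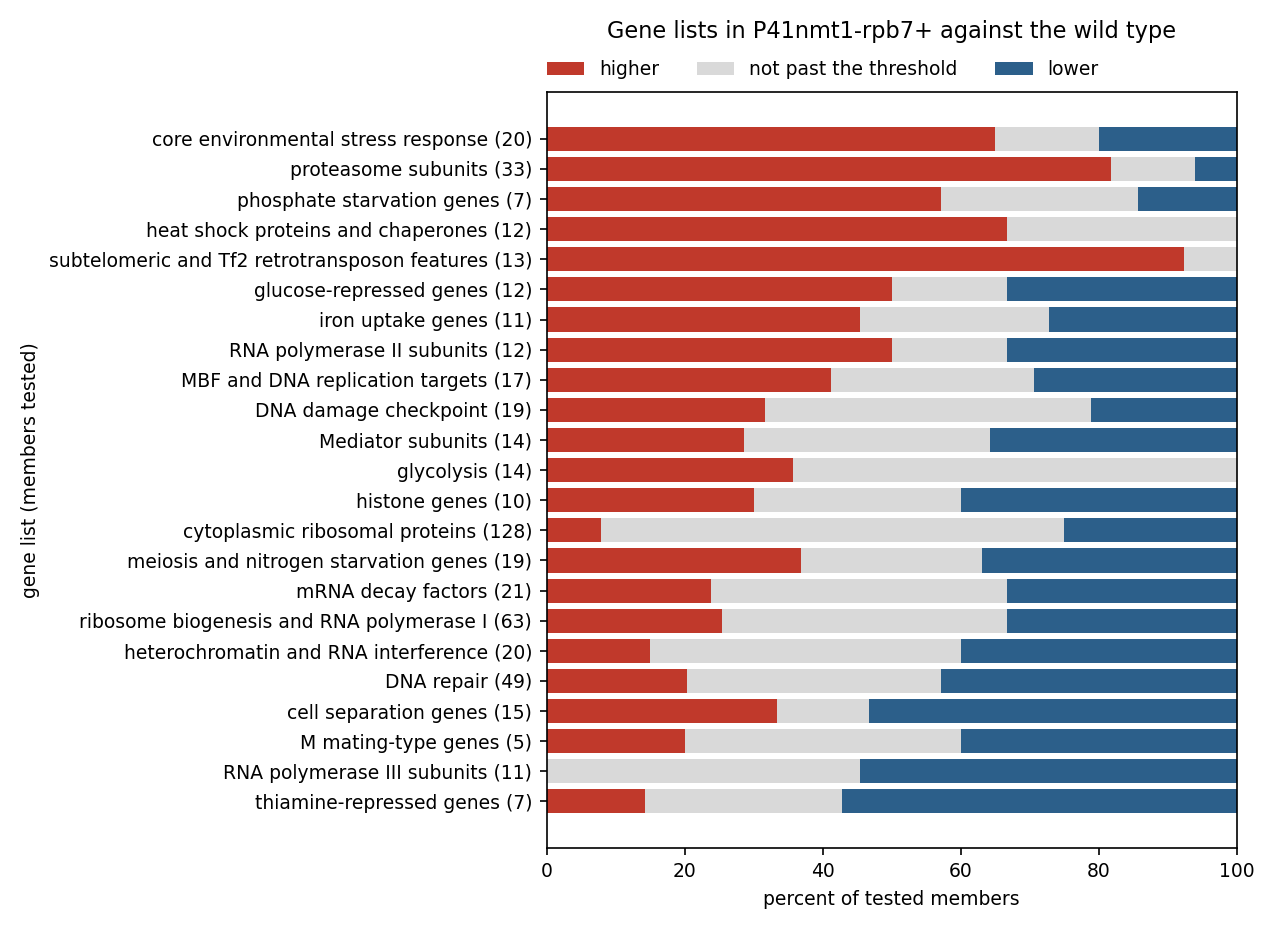
Percent of the tested members (horizontal axis) of each gene list with at least 4 tested members that were higher, lower or not past the threshold (limma, adjusted p under 0.05) in P41nmt1-rpb7+, ordered by the list's median log2 fold change, with the number tested in parentheses. Proteasome subunits (27 of 33 higher) and subtelomeric and Tf2 features (12 of 13 higher) have the largest shares of higher genes.

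Both wild-type arrays were read in one scan and both P41nmt1-rpb7+ arrays in another, so scan and strain cannot be told apart, and p-values measure only the spread between 2 arrays of one scan. Of the genes named with a measured level, put4, cab4 and rad15 were well above background on only 1 P41nmt1-rpb7+ array, and rpb3, pre8, cut8, spo12, shu1, tgp1, rpl1603, tlh2, hrr1 and str2 on only 1 wild-type array. The number of arrays, 2 per strain, limits the precision of each value. No probe could be placed on its gene, so a probe near background in the wild type may not report the gene's mRNA level. This bears on cdc31, utp24, rad21, dcp2, rpb3 and pre8, among others.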

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

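The tests of the spike-in amount and of mitochondrial features were set out before their results were seen, and the test of labelling without poly(A) tails only after. The E1A spike-in controls, RNAs of known sequence added during labelling and used only in the alternative scaling, were flagged because their signal was higher on the P41nmt1-rpb7+ arrays than on the control arrays of the wild type. Over the 4 spike-in probes that were above background and unsaturated on all arrays, the mean log2 shift against the 75th percentile was 2.53, or 5.76-fold, with single probes between 1.98 and 3.10.

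A candidate explanation is that the P41nmt1-rpb7+ samples held less RNA polymerase II mRNA per unit of total RNA, which would raise the spike-ins and the transcripts of the mitochondrial genome together. The 34 mitochondrial features did rise, with a median log2 fold change of 4.10, which is more than the spike-ins, while nuclear tRNA features rose by a median of 1.61, which is less. Labelling that took up more RNA without poly(A) tails would raise the nuclear tRNAs with the mitochondrial features, but above coding features of the same brightness they rose by a median of only 0.42, against 3.60 for the mitochondrial features. Coding features at background in the wild type were tested only if bright in P41nmt1-rpb7+, so 0.42 may be too low. Without matching, the medians were 1.61 and 4.10, and a part of such labelling was not excluded. Another amount of spike-in RNA cannot be told apart from a lower mRNA share, because either alone would move all spike-in probes by 1 factor. The probes' shifts differed 4.94 times as much as arrays of one strain did, which goes against either as the whole reason. With 4 probes, the 95% interval of that ratio, 2.12 to 18.8 and computed after the ratio was seen, held the bound of 3 set beforehand, so neither was excluded. The scan is confounded with the strain and stays open.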

How the results depend on the processing

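The lower level of rpb7 kept its direction and stayed past the threshold under every alternative that tested it, with log2 fold changes from −2.84 to −2.35 when an array was left out (adjusted p 0.00161 to 0.00405) and from −2.60 to −2.43 under the others. With E1A spike-in scaling it was −5.12, or −2.65 once the median of all genes was taken off. Of the 115 named genes, none reversed relative to the median of all genes. At most 4 of those tested lost their call in any refit at the same threshold, the most with quantile normalisation. They were chosen among the largest called changes of the main fit, so kept calls are a weak check. With E1A spike-in scaling the median log2 fold change was −2.46, the genes called were 252 higher and 5053 lower against 2139 and 1851, and 28 of the 64 named increases became decreases unless that shift was taken off. The share of higher genes among calls was 4.75% with spike-in scaling and otherwise 46.4% (quantile normalisation) to 59.3% (median scaling), against 53.6%. A minimum change of 2-fold left 1738 genes, 1020 higher and 718 lower, and would drop named genes with smaller changes, such as rad3 (0.92) and hxk1 (0.38). When probes had to be above background on all arrays, 74 named genes were left to test and each kept its call. With specific-tag probes only, 90 were left, without rpb7, rad4, rad1, rad3 and rhp18, and each kept its call. Counts with an array left out were 3431 to 3608 genes, 1829 to 1934 higher and 1560 to 1708 lower, with 2 to 3 lists past the threshold and 112 to 115 named genes called.

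Of the gene lists, 2 passed, 0 with an estimated correlation, and 1 with probes above background on all arrays, or with specific-tag probes only, which left too few Tf2 features to test. The tests of lists with spike-in scaling, which 0 passed (adjusted p = 0.891 for the proteasome and 0.634 for the subtelomeric and Tf2 features), carried the shift of all genes and so say nothing about a list. With that shift taken off, 1 passed, the proteasome (adjusted p = 0.00271), and the subtelomeric and Tf2 features did not (adjusted p = 0.0549). The specific-tag setting and the shift taken off were chosen after seeing the data. The self-contained test (fry) was run only on the main fit, so its dependence on the scaling was not checked. The proteasome median relative to all genes was 0.56, 0.54 to 0.58 with an array left out, and 0.39 (quantile normalisation, adjusted p = 0.0166) to 0.61 (specific-tag probes) under the others. Spike-in scaling and an estimated correlation (adjusted p = 0.926) leave this median in place by their design, at 0.56 in both. The median of the subtelomeric and Tf2 features, 0.39 relative to all genes and 0.38 to 0.44 with an array left out, was 0.24 with quantile normalisation (adjusted p = 0.153), 0.39 with spike-in scaling, 0.39 with probes above background on all arrays (adjusted p = 0.0501) and 0.39 with an estimated correlation (adjusted p = 0.926). The cause was not tested. Cytoplasmic ribosomal proteins passed with quantile normalisation (adjusted p = 0.0404) and without wild type replicate 1 (adjusted p = 0.0214), and heat shock proteins without wild type replicate 2 (adjusted p = 0.0194). The replicate block left 3895 genes, rpb7 at −2.59 (adjusted p = 0.00216) and both lists past the threshold, and the deviations of same-numbered arrays correlated at only 0.08, so the numbers did not pair the arrays. Where an array was left out, the lone array of its strain was assumed to vary like the others. Signal over background limits the dim genes, since negative controls were brighter on the P41nmt1-rpb7+ arrays (processed signal 21.8 and 24.7) than on the wild type's (10.2 and 15.6).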

Other observations

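All tests in this part were chosen after the data were seen. Every feature of the mitochondrial genome that was tested rose in P41nmt1-rpb7+, 24 of 24 tRNAs and 10 of 10 others. The cytochrome b gene cob1 was 30.5-fold higher and the cytochrome oxidase genes cox1 and cox3 13.0-fold and 7.76-fold. The median log2 fold change was 4.53 for the tRNAs (camera, adjusted p = 5.18e-10; adjusted p = 0.462 with an estimated correlation) and 3.45 for the others (adjusted p = 4.52e-05; 0.462 with an estimated correlation). No class passed with an estimated correlation, not even these tRNAs, so that form of the test says little about any class. Nuclear genes of the respiratory chain and ATP synthase did not follow, with 15 of 43 higher and 16 lower (median −0.06, adjusted p = 0.589), nor did genes for mitochondrial ribosomal proteins, with 24 of 69 higher and 24 lower (median 0.07, adjusted p = 0.945). Nuclear tRNA features were higher in 40 of 49 cases (median 1.61, adjusted p = 6.27e-07; 0.524 with an estimated correlation), but their median rise above coding features of the same wild-type brightness was only 0.42. Antisense RNAs were higher in 200 of 389, with 103 lower (median 0.48, adjusted p = 0.0406; 0.602 with an estimated correlation). The array holds 693 antisense features, and 46 of those tested were not well above background on either wild-type array. These entered only because they were bright in P41nmt1-rpb7+, and features dim only in P41nmt1-rpb7+ could enter likewise. The class was not compared with coding features of the same brightness, so a part of its rise may come from the filter.

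Amino acid permease and transporter genes fell, 12 of 18 lower and 1 higher, with a median of −0.88 (camera, adjusted p = 0.00581; adjusted p = 0.462 with an estimated correlation). Besides put4 and isp5 these included SPAC1039.01 (10.3-fold lower), aat1 (7.49-fold), per1 (4.56-fold) and agp3 (2.49-fold). Of 31 aminoacyl-tRNA ligase genes, 16 were lower and 6 higher (adjusted p = 0.0680), and of 11 cell surface glycoprotein genes 6 were lower and 2 higher (adjusted p = 0.139). Other classes that did not pass were intergenic RNAs (adjusted p = 0.693), splicing factors (0.945), translation initiation factors (0.693), ubiquitin ligases and hydrolases (0.191) and meiotically upregulated genes (0.0758).

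Genes that fell at least 2-fold were more frequent near chromosome ends, though not at all of them. Among the 60 outermost tested coding genes at each of the 6 ends, 27.8% fell at least 2-fold, against 11.1% of the other 4280 (Fisher's exact test, two-sided, p = 1.19e-16; neighbouring genes are not independent), with 45.0% at the left and 36.7% at the right end of chromosome I and 21 of 60 genes at the left end of chromosome II, but 11.7% at its right end. On chromosome III the shares were 16.7% at the left end (adjusted p over the 6 ends = 0.252) and 21.7% at the right end (adjusted p = 0.0303). Dimmer probes near the ends did not account for this, since the share was 16.1 percentage points above that of interior genes matched on wild-type brightness, whose 10000 random draws reached at most 18.6%. Loss of chromosome-end DNA would take the signal to background, but 80 of the 100 fallen genes, 80% (exact 95% interval 70.8% to 87.3%), stayed well above background on both P41nmt1-rpb7+ arrays. This goes against loss for most of these genes. The count pools all 6 ends, so loss of a short stretch at a single end was not excluded. The fallen genes near the ends included the permease and transporter genes put4, isp5, SPAC1039.01, aat1 and agp3, though not per1. This pattern and the fall of the permease genes thus share members, and position and gene function were not separated. A response of subtelomeric genes to low Rpb7 may be the reason and was not tested, and the scan stays open.

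Another group of 148 genes was not well above background in the wild type but was called higher in P41nmt1-rpb7+, and it includes genes of general function such as utp24, cdc31 and dcp2. The median log2 fold change was 3.63, or at least 2.77 when the wild type was set to the floor, against a shift of the negative controls of 0.94, but the choice of the set favours large changes (lowest 1.27). The set's median signal lay 2.05 in log2 above the background floor of the P41nmt1-rpb7+ arrays (median absolute deviation 0.77, lowest 0.71). Its genes were tested only because they were well above background on both of these arrays. A signal above that floor was thus given by the choice, and the higher floor was not excluded as a part of the reason. Introns are AT-rich, but the mean GC content of the set's 74 coding-gene probes was 2.24 percentage points above that of other coding genes. This goes against probes in introns for the set as a whole. A mean cannot exclude them for a part of the set, and no probe was placed on its gene. Cross-hybridising probes could account for a part, if that is what the tag Xhyb, whose meaning is not stated, marks. It is carried by 45.3% of these probes against 37.7% of the other features not above background (Fisher's exact test, one-sided, p = 0.0473). The tag Spec is carried by 81 of the 148, and a biological explanation was not tested.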
